A study of Zea mays with 6 samples.

How the data were processed

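RNA from mature anthers of maize (Zea mays, line B104) was sequenced as 6 libraries, 3 from wild type and 3 from plants labelled as lacking function of both ZmCOI2a and ZmCOI2b. Groups and replicate numbers were taken from the sample labels. The labels do not say whether the libraries of a genotype came from separate plants, so p-values measure the spread between these samples, which may be partly technical.

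The deposited values are FPKM (fragments per kilobase of gene, scaled to library depth), with 1 value per gene and library, gene positions, strand and span, per the file headers. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.3 and HTSeq 0.6.0, and the genome build B73 RefGen_v4, without saying what each tool was used for. Strand setting, filters and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and reads of near-identical gene copies are uncertain. The files list 31470 genes, the same in all 6 libraries, and no listed gene was at 0 in every library.

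Whole reads were recovered from the FPKM values of the authors. For each gene, the whole-number counted length was sought for which value times length times library total gave whole reads in all 6 libraries, within 0.0001 reads plus 3e-09 per read. This gave whole reads for 31465 genes, and 5 genes had no solution. Among 2000 genes drawn at random, 99.95% were solved, against 2.05% after the values had been perturbed. Reads of a gene that share a divisor with its length can come out divided by it. The recovered reads made up 99.7 to 99.8% of each library total. The library totals were 17589318, 17555615 and 17759978 reads for mutant replicates 1, 2 and 3, and 17280264, 16845656 and 17632330 for wild-type replicates 1, 2 and 3. The values do not show whether a read stands for a single read or a pair. At these depths, 1 read in a gene of 1000 bp corresponds to between 0.0563 and 0.0594 FPKM. Floors of 3 reads and intervals on read ratios cover counting error only.

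Gene identifiers were used as the files give them. Of the identifiers, 30950 begin with Zm00001d, and the files do not pair them with gene names. A RefSeq gene table of the newer assembly Zm-B73-REFERENCE-NAM matched 19 identifiers, all of microRNA loci, and 0 of those beginning with Zm00001d. None of its coordinates were used. The 29 gene lists fixed before the data were examined therefore had 0 matched members and were not tested, the families by gene description were not tested, and the targeted genes were not analysed here, so the genotype labels were not checked on the targeted transcripts.

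The planned test was a count model on gene counts, with limma on log2(value + 1) as the fallback for normalized values. The files hold FPKM, so the fallback was used. The planned count model included TMM scaling of the libraries, and neither was run on the recovered reads. The fallback keeps the scaling of the deposited FPKM, and the balance of rises and falls depended on this choice. It gave 361 rises and 901 falls. Limma-voom on the recovered reads with median-of-ratios scaling, chosen after seeing the data, gave 678 and 389. Genotypes were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the spread and no other covariate, over all 6 libraries. Fold changes are on this scale, which understates the change of genes with low values. Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 18984 genes. This filter replaced the planned count filter and was set after the files had been opened and first fits run. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and calls with an absolute log2 fold change of at least 1 were counted as well. Each limma test is two-sided.

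The test was tried on simulated reads for 19027 genes with the means and depths of these libraries. It called 37 of 97 genes changed 2-fold (38.1%), 87 of 92 genes changed 4-fold (94.6%) and 18 genes that had not been changed. Each simulated gene took a spread averaged over genes of similar abundance, and the libraries were drawn independently. Spread particular to a gene and shifts of whole libraries were therefore absent, so these shares need not hold for the real libraries.

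The rule for named genes, fixed before the data were examined, took called genes with a CPM of at least 5 in the higher group and no overlap between groups, ranked by fold change, and the 5 most abundant genes. Its requirement of a gene name or description could not be met by Zm00001d identifiers, so it was left out, and only 2 rising and 2 falling identifiers are printed. Loci named only by position were chosen after their values had been seen, except for the 5 most abundant genes.

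Alternatives fixed before the data were examined were median-of-ratios and upper-quartile scaling, limma-voom on the recovered reads, no filter, a filter of CPM 1 in 3 libraries, an adjusted p under 0.01, a test against a 2-fold change, a replicate block, removal of the 20 most abundant genes, other sizes of the set of most abundant genes, and each library left out in turn. Other pseudocounts, the TPM scale, a filter of FPKM 5, no intensity trend, limma-voom with median-of-ratios scaling, and all settings for gene classes, neighbouring genes and genes read in 1 genotype were chosen after seeing the data. Shares of reads were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. The 16 gene classes were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation. Neighbouring calls were compared with 10000 one-sided permutations of the calls over the tested genes, and windows of 2 Mb holding at least 5 tested genes with one-sided hypergeometric tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.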

Results

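Transcripts of mature maize anthers were measured by RNA sequencing in 3 wild-type libraries and 3 libraries of a ZmCOI2a and ZmCOI2b double mutant, all in the inbred line B104. COI proteins are F-box receptors of the hormone jasmonate, and the title of the series places the 2 genes in anther opening and male fertility. The comparison asks which transcripts differ between anthers with and without both genes. Depth was similar across libraries, between 16845656 and 17759978 reads counted on genes. The first principal component, with 52.8% of the variance, separated the genotypes. Mutant replicate 3 lay at -21.9 on it, nearer to wild type than mutant replicates 1 and 2 at -42.9 and -46.3. The wild-type libraries lay at 24.3, 41.0 and 45.8, and wild-type replicates 2 and 3 stood far apart on the second component (25.8%), at -37.1 and 47.3. Across genes, which are not independent replicates, Pearson's r was 0.942 to 0.985 between libraries of the same genotype and 0.924 to 0.964 between genotypes.

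**Figure D1:**
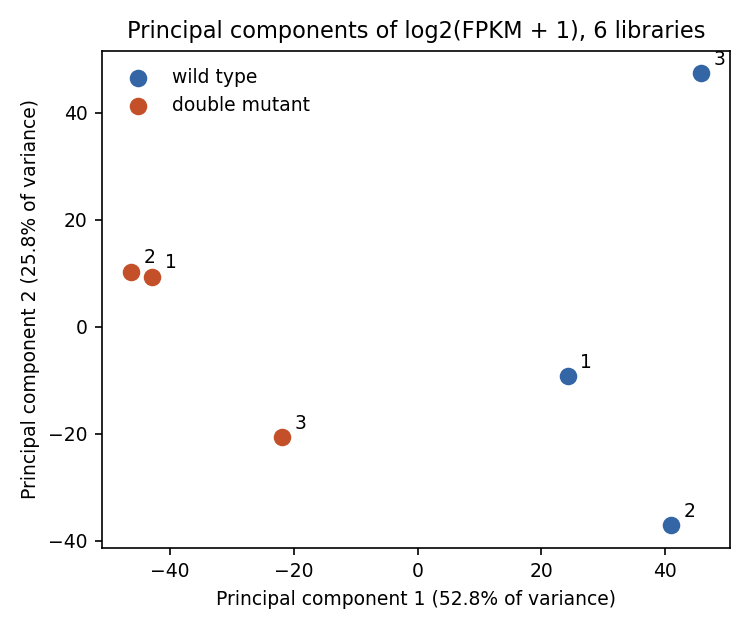
Principal components of log2(FPKM + 1) for the 3 wild-type (blue) and 3 double-mutant (red) libraries, numbered by replicate. The axes hold 52.8% and 25.8% of the variance, and the genotypes lie on opposite sides of 0 on the first axis.

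Of 18984 tested genes, 1262 changed in the mutant (limma, adjusted p under 0.05): 361 rose and 901 fell, and 273 of the rises and 446 of the falls were at least 2-fold. The balance between rises and falls depended on the scaling. With FPKM as deposited, the median log2 fold change of the tested genes was -0.20 and 28.6% of the calls were rises. With median-of-ratios scaling the median was 0.03, 661 genes rose and 410 fell (61.7% rises), and with upper-quartile scaling 560 rose and 596 fell (48.4% rises). Called the same way under these 3 scalings were 361 rises and 410 falls. These are all the rises called with FPKM as deposited and all the falls called with median-of-ratios scaling. The scalings mainly shift the fold changes of all genes, so the overlap is not agreement of separate checks. The number of calls rested on single libraries: it was 54 without mutant replicate 1, 50 without mutant replicate 2, 840 without mutant replicate 3, 409 without wild-type replicate 1 and 490 without wild-type replicate 2. Without wild-type replicate 3, 634 genes rose and 739 fell. With no filter on low values, 292 of 31470 genes were called.

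**Figure D2:**
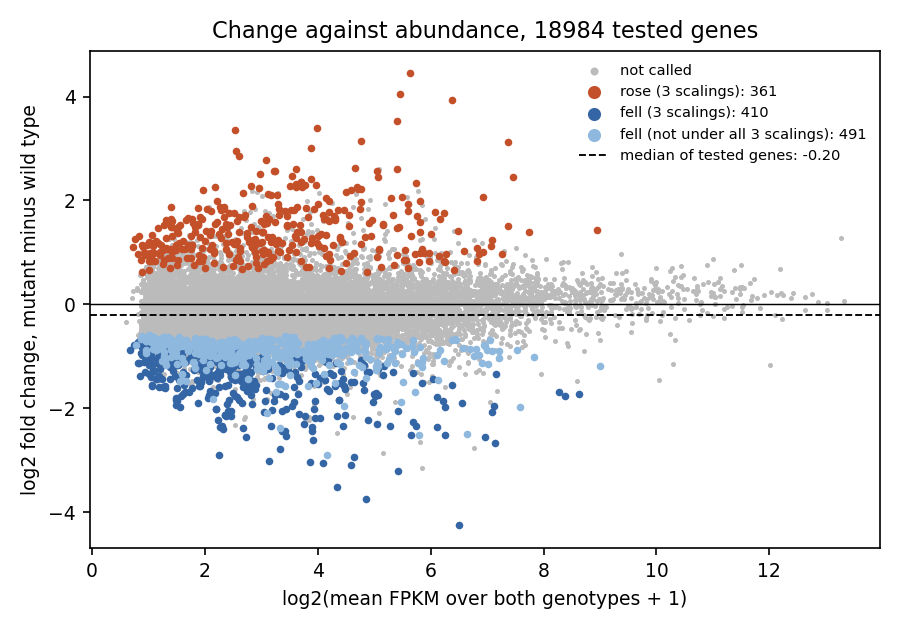
Log2 fold change (mutant minus wild type, on log2(FPKM + 1)) against log2 of the mean FPKM over both genotypes plus 1, for 18984 tested genes. Red points are the 361 genes that rose and dark blue points the 410 that fell under the 3 scalings, light blue points fell with FPKM as deposited but not under all 3, and the dashed line is the median of -0.20.

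The files do not pair gene identifiers with names, so the genes that moved most are given by identifier and position on B73 RefGen_v4. Among called genes whose genotypes did not overlap, the largest rise on the log2(FPKM + 1) scale, which understates genes with low values, was at Zm00001d052673 (chromosome 4, 196893203 to 196896534), from 3.16 ± 2.31 FPKM in wild type to 93.8 ± 53.0 in the mutant (SD, n = 3 each). Its log2 fold change was 4.45 (SE 0.57, limma adjusted p = 0.0121), and the call was lost without mutant replicate 1 (adjusted p = 0.0531) and without mutant replicate 2 (adjusted p = 0.0727). With 1 library left out, its log2 fold change ran from 4.03 to 5.06. Zm00001d014914 (chromosome 5, 68025894 to 68027081) rose from 3.99 ± 1.81 to 82.3 ± 34.4 FPKM, a log2 fold change of 4.05 (SE 0.37, limma adjusted p = 0.00529). The largest fall on that scale was at Zm00001d044864 (chromosome 9, 5827581 to 5828567), from 170 ± 148 to 9.26 ± 10.7 FPKM. Its log2 fold change was -4.25 (SE 0.83, limma adjusted p = 0.0301), and the call was lost with no filter (adjusted p = 0.0705), without mutant replicate 1 (0.0902), without mutant replicate 2 (0.126) and without wild-type replicate 2 (0.0560). With 1 library left out, its log2 fold change ran from -5.10 to -3.55. Zm00001d013783 (chromosome 5, 20028246 to 20077272) fell from 53.0 ± 12.5 to 3.11 ± 1.33 FPKM, a log2 fold change of -3.74 (SE 0.27, limma adjusted p = 0.00305), and was called in all 21 alternative settings run for it. In the planned test against a 2-fold change, the calls of Zm00001d052673 (adjusted p = 0.183), Zm00001d014914 (0.0630) and Zm00001d044864 (0.636) were lost.

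**Figure D3:**
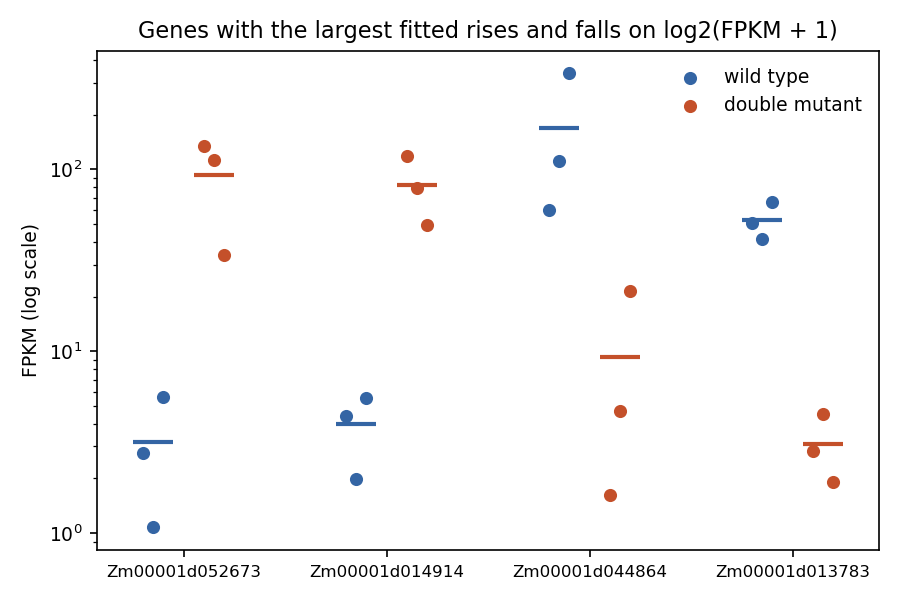
FPKM on a log axis in each of the 3 wild-type (blue) and 3 double-mutant (red) libraries for the 2 called genes with the largest rises and the 2 with the largest falls on the log2(FPKM + 1) scale, among genes picked for genotypes that do not overlap. Points are libraries and bars are group means.

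The most abundant transcript of these anthers came from a gene on chromosome 1 (76658393 to 76659887). It held 1.95 ± 0.41% of all gene reads in the mutant and 0.831 ± 0.283% in wild type (SD, n = 3 each), with every mutant library above every wild-type library. Its log2 fold change of 1.27 (SE 0.34) missed the threshold (limma adjusted p = 0.0584). It passed in 3 alternative settings, among them limma-voom (adjusted p = 0.0427), and missed in the other 17. Those 17 include median-of-ratios and upper-quartile scaling (limma adjusted p = 0.0629 and 0.0729) and each library left out. The next 4 most abundant genes differed by less than the spread between replicates, with log2 fold changes between 0.04 and 0.17 and limma adjusted p between 0.721 and 0.953, and the sign of each turned without wild-type replicate 2. The 20 most abundant genes together held 9.56 ± 0.69% of reads in the mutant and 8.14 ± 0.94% in wild type (SD, n = 3 each, exact permutation p = 0.1, the smallest this design allows). The difference of 1.42 percentage points was 0.878 without wild-type replicate 2. Most of the difference came from the chromosome 1 gene above, at 1.95% against 0.831%, so it is not a separate result.

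MicroRNA loci were the only identifiers that could be matched to names. Of 7 tested, 0 were called by limma and 0 by limma-voom, and 1 had an unadjusted p under 0.05. The tested MIR156 loci had at most 5 reads in each library and MIR396a 4 to 16, so the lack of calls there says little. The most highly read was MIR168a (chromosome 5, 76534928 to 76535031), whose mature product targets ARGONAUTE1 transcripts, at 158, 142 and 58.5 FPKM in the mutant libraries and 75.7, 41.7 and 76.9 in wild type (log2 fold change 0.80, limma adjusted p = 0.228). MIR168b (chromosome 4, 244520636 to 244520739) had 22, 12 and 6 reads in the mutant libraries and 4, 4 and 6 in wild type (limma adjusted p = 0.108). It was called in 1 alternative setting, without mutant replicate 3 (limma adjusted p = 0.0381), and not in the other 18. The reads at these loci come from RNA sequencing libraries and do not measure the mature microRNAs.

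A few genes, sought after the data had been seen, were read in 1 genotype and hardly or not at all in the other. With at most 1 read in each library of one genotype and at least 10 in each library of the other, 9 genes were read in the mutant only and 7 in wild type only. Of these 16 genes, 5 passed the abundance filter, and all 5 were called by limma. They were picked on the same libraries for reads that separate the genotypes, so these calls add no support. A gene on chromosome 3 (167821561 to 167825000) had 324, 411 and 277 reads in the mutant and 1, 1 and 0 in wild type, a depth-corrected ratio of 495 (95% counting interval 137 to 4093). A gene on chromosome 7 (125510140 to 125512430) had 0, 0 and 1 reads in the mutant and 107, 208 and 466 in wild type, a ratio of 798 (143 to 31571). A gene on chromosome 1 (224114594 to 224117804) had 0 reads in each mutant library and 35, 42 and 118 in wild type, at least 66.4-fold higher against a floor of 3 reads over the mutant group. The limits of at most 1 and at least 10 reads decide the number: 0 against 10 gave 4 genes, at most 1 against 20 gave 4, and at most 2 against 10 gave 31. Leaving out 1 library, which loosens the rule, gave 21 to 39.

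With FPKM as deposited, 2 windows of the genome held more falls than others, a search made after the data had been seen. On chromosome 2 between 48 and 50 Mb, 6 of 11 tested genes fell, all between 49052848 and 49811410, with log2 fold changes from -1.65 to -0.70 (hypergeometric adjusted p = 0.00409 over 966 windows). On chromosome 3 between 26 and 28 Mb, 5 of 11 fell, between 27133419 and 27550063, with log2 fold changes from -2.91 to -0.78 (adjusted p = 0.0418). With median-of-ratios scaling, 4 of 11 and 3 of 11 fell, and neither window passed (adjusted p = 0.0606 and 0.409). Over all 18984 tested genes, 901 fell with all 6 libraries. Without mutant replicate 3, 1 of 11 fell on chromosome 2 and 4 of 11 on chromosome 3, beside 542 falls over all tested genes. Without wild-type replicate 1 these were 2 and 3 (273 falls over all). They were 2 and 2 without wild-type replicate 2 (330 falls) and 4 and 3 without wild-type replicate 3 (739 falls). Without mutant replicate 1 or 2 they were 0 and 0, with 24 and 25 falls over all tested genes.

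**Figure D4:**
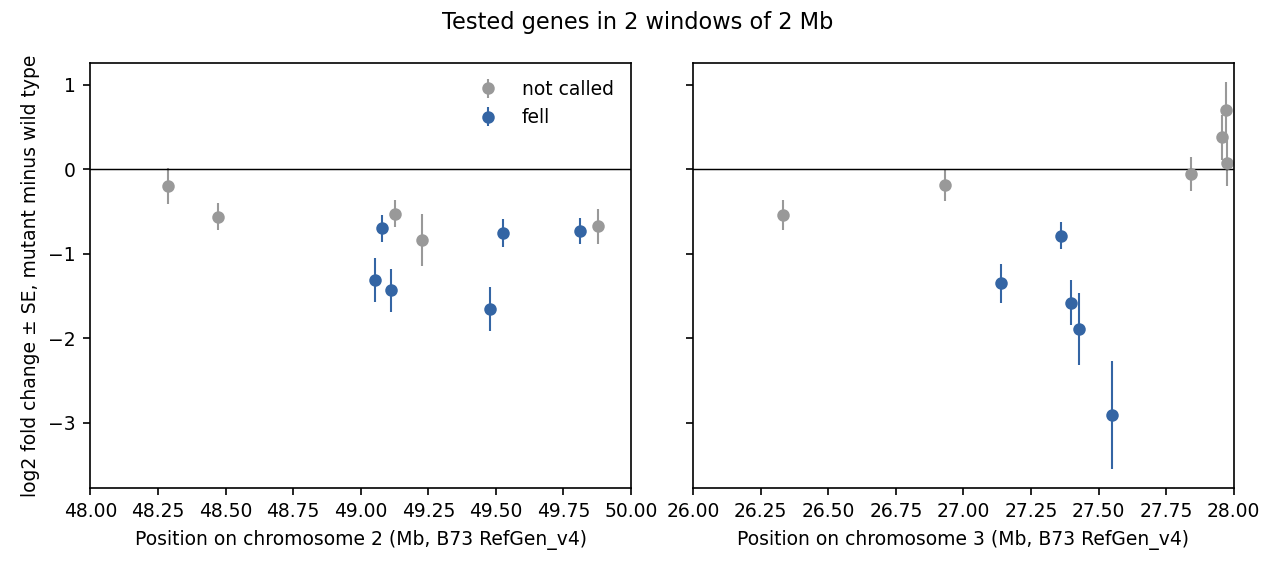
Log2 fold change (mutant minus wild type, with SE) of the 11 tested genes in each of 2 windows of 2 Mb, by position on B73 RefGen_v4. Blue points are the 6 genes on chromosome 2 and the 5 on chromosome 3 that fell with FPKM as deposited.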

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

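The genes in this part were sought only after the data had been seen. Of the 16 genes read in 1 genotype only, 11 lay below the abundance filter and so were outside the comparison of genotypes, 6 of them read in the mutant and 5 in wild type. They drew attention because they carry reads in data that the test left out. Among them, a gene on chromosome 1 (10028217 to 10030507) had 37, 51 and 12 reads in the mutant and 0 in each wild-type library, at least 32.6-fold higher against a floor of 3 reads over the wild-type group. A gene on chromosome 4 (21165647 to 21166729) had 0, 1 and 1 reads in the mutant and 15, 16 and 84 in wild type, a ratio of 58.8 (95% counting interval 15.9 to 491). Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 16 such genes, the real one, and the highest of the others gave 1. With 10 splits, no share under 0.05 can be reached.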

How the results depend on the processing

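The FPKM filter, the other pseudocounts, the TPM scale, the filter of FPKM 5, voom with median-of-ratios scaling, the 3-scaling counts and all settings for the last 4 results below were chosen after seeing the data. Against 1262 changed genes (361 rose, 901 fell), no filter gave 292 (125 and 167), FPKM of 5 in 3 libraries 748 (230 and 518), adjusted p under 0.01 47 (27 and 20) and a test against a 2-fold change 4 (3 and 1), each with other thresholds or genes tested. Median-of-ratios scaling gave 661 rises and 410 falls, upper quartile 560 and 596, and voom with median-of-ratios scaling 678 and 389. These scalings shift the fold changes of all genes, which moves the balance by construction. The median log2 fold change was -0.20 as deposited, 0.03 with median-of-ratios and -0.06 with upper-quartile scaling. Which scaling suits these anthers better was not tested. The replicate block gave 715 changed genes (247 rose, 468 fell). Same-numbered libraries did not deviate together (correlations 0.01, -0.38 and -0.33), which gives no sign that the numbers pair them. With 3 libraries per group, a smaller effect of a shared day or batch could be missed, so pairing is not excluded. Leaving out 1 library gave 50 to 1373 changed genes, 25 to 634 rises and 24 to 739 falls, and under the 3 scalings 25 to 619 rises and 23 to 381 falls, with fewer samples. The difference in the share of the 20 most abundant genes was 0.878 to 1.76 percentage points. Over the 14 settings that refit the fold changes, the values of the single genes named kept their direction and side of the threshold 196 times, lost the call 5 times, gained it 3 times and changed sign 15 times, in genes called in neither setting. The other 7 settings leave fold changes as they are and can only move calls, with 6 lost and 1 gained. Without 1 library, the log2 fold changes of the 4 genes next to the most abundant ran from -0.044 to 0.34, -0.20 to 0.28, -0.061 to 0.32 and -0.31 to 0.34, that of MIR156d from -0.37 to 0.066, MIR156h from -0.65 to 0.0028, MIR156j from -0.17 to 0.70 and MIR396a from -0.18 to 0.56. The tested MIR156 loci had at most 5 reads in each library, so their fold changes carry little weight. MIR156d was at 0.0010 with median-of-ratios scaling and 0.11 with voom and that scaling. The cause was not tested. Genes read in 1 genotype only numbered 4 with 0 against 10 reads, 4 with 1 against 20, 31 with 2 against 10, and 21 to 39 without 1 library. The odds ratio of a rise for single-segment genes was 2.03 to 3.77 without 1 library. Pairs that both fell, observed over expected, ran from 0 (without mutant replicate 2) to 32.4 (without mutant replicate 1) where few genes were called, and were 1.03 without wild-type replicate 1. The difference of medians of the 1000 most abundant genes was 0.35, with adjusted p = 0.543 with an estimated correlation. The planned gene lists, gene families and targeted genes were not run for lack of names. Of the planned count-based tests, limma-voom was run on the recovered reads and the others were not run. At this depth and with 3 libraries per group, 38.1% of simulated 2-fold changes were called, and neither depth nor group size was varied. The simulation left out spread particular to a gene and shifts of whole libraries, so the share for the real libraries may differ.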

Other observations

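The median-of-ratios scaling, the removal of the 20 most abundant genes and the leaving out of each library were planned for the counts of changed genes. Their use as tests of an explanation, the bounds they were read against, and the tests on single-segment genes, the 1000 most abundant genes, mitochondrial reads, mutant replicate 3 and neighbouring genes were chosen only after the result had been seen. Genes counted over a single segment (counted length equal to their span) rose more often than others: 111 of 3279 (3.39%) against 250 of 15705 (1.59%), an odds ratio of 2.17 (Fisher's exact test p = 2.26e-10, over genes, which are not independent replicates). Falls were at 5.34% against 4.62% (odds ratio 1.16, Fisher's exact test p = 0.0861), with an odds ratio of 1.69 (p = 1.15e-05) after median-of-ratios scaling, and 1.46 (p = 0.000216) after upper-quartile scaling, while 4.27% against 5.61% fell with limma-voom (p = 0.00163), so the direction of the falls depended on the setting. The odds ratio of a rise was 1.67 (95% interval 1.27 to 2.198) within 25 bins of length and abundance, and 1.33 (0.987 to 1.79) in those bins without mutant replicate 3. In those bins the odds ratio of a fall was 0.743 (0.612 to 0.901), and 0.767 (0.624 to 0.943) with limma-voom. It was 1.03 (0.791 to 1.34) after median-of-ratios scaling and 0.899 (0.717 to 1.13) after upper-quartile scaling. As a class these genes did not pass camera (adjusted p = 0.108 over 16 classes). The 1000 most abundant genes had a median log2 fold change of 0.14 against -0.21 for the others (camera adjusted p = 7.09e-12, and adjusted p = 0.543 with an estimated correlation), and they held 60.7 ± 1.4% of reads in the mutant and 55.6 ± 2.8% in wild type (SD, n = 3 each, exact permutation p = 0.1). Reads of 46 listed mitochondrial-genome genes came to 3.74 ± 0.61 CPM in the mutant and 7.59 ± 2.33 in wild type (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). These are 64, 56 and 78 reads in the mutant libraries and 97, 118 and 179 in wild type. Of 2 other sets run, 12 plastid-genome genes had 0.28 against 0.25 CPM (exact permutation p = 0.9). The 448 identifiers beginning with ENSRNA had 361 in the mutant against 528 in wild type (exact permutation p = 0.3). Both sets were also chosen after the data had been seen.

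Chance was examined by splitting the 6 libraries in other ways. The real split gave 1262 changed genes by limma and 1405 by limma-voom, and the highest of the other 9 gave 0 by either tool, with at most 2047 genes at an unadjusted p under 0.05 against 5403 for the real split. Only 1 of the 10 splits, the real one, gave as many calls, and with 10 splits no share under 0.05 can be reached. Each of the other 9 splits mixes the genotypes within its groups. A genotype difference then widens the spread and lowers the calls, so their 0 is not a level of calls made by chance.

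More genes fell than rose with FPKM as deposited. Removing the 20 most abundant genes left 31.3% rises and a median log2 fold change of -0.18, against -0.20 with them. This argues against these 20 genes alone as the whole cause. Their share of reads differed by only 1.42 percentage points, so their removal could shift the other genes only a little. It does not address a shift of composition over more genes: the 1000 most abundant held 60.7% of reads in the mutant and 55.6% in wild type. The per-million scaling of the deposited values cannot be told apart from a real excess of falls: 61.7% of calls were rises after median-of-ratios scaling, but that scaling recentres all genes (median log2 fold change from -0.20 to 0.03) and so moves this share by construction. Without wild-type replicate 3, 46.2% of calls were rises, without mutant replicate 1 they were 30 of 54 and without mutant replicate 2 25 of 50, and without mutant replicate 3, wild-type replicate 1 and wild-type replicate 2 they were 35.5%, 33.3% and 32.7%, which leaves a part of wild-type replicate 3 open. A real excess of falls in the mutant stays open.

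Mutant replicate 3 lay between the other mutant libraries and wild type. A wild-type library under a mutant label is argued against: of 17 genes absent from wild type and read in mutant replicates 1 and 2, 16 (94.1%) were read in it. Wild-type material mixed in at 1 proportion cannot be told apart from a milder mutant state: 22 genes absent from the other 2 mutant libraries had 110 reads in it against 93.0 expected and 2 of them lay below the reads such a mixture needs, but these genes were picked on the other libraries, so the total supports neither reading. A first version of this test had argued against a mixture, because genes that rose without this library lay 48.8% of the way to wild type and genes that fell 23.2%, a gap of 25.5 points. It was replaced after that result was seen, although its successor picks genes in the same way, and a later run on every other library gave gaps of 2.54 and -19.5 points for mutant replicates 1 and 2 and 44.3, 39.0 and -48.0 for wild-type replicates 1, 2 and 3. With median-of-ratios scaling the gaps were 11.3, -33.7 and 20.6 points for mutant replicates 1, 2 and 3. For wild-type replicates 1, 2 and 3 they were then 36.2, 40.5 and -9.78. The gaps of mutant replicates 1 and 2 rest on only 24 to 30 genes in each direction.

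Genes that fell lay next to each other more often than shuffled calls, in 62 neighbouring pairs against 42.5 expected (permutation p = 0.0019), but without wild-type replicate 1 there were 4 pairs against 3.90 expected (p = 0.552). Pairs that both rose numbered 11 against 6.81 expected (permutation p = 0.0831), and with median-of-ratios scaling 15 pairs both fell against 8.82 (p = 0.0345) and 36 both rose against 22.9 (p = 0.0055), so with that scaling the clustering was not particular to falls. Shared reads of touching gene models are argued against as the whole cause, since 57 pairs lay at least 1000 bp apart against 39.0 expected (permutation p = 0.0033). Segments of another haplotype carried along with the mutant alleles may also place changed genes side by side, changing them in both directions, and 36 neighbouring pairs had opposite calls against 34.2 expected (permutation p = 0.395), which leaves this open. Joint regulation of neighbouring genes was not tested.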
